A study of Homo sapiens with 42 samples.

How the data were processed

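Single nuclei of developing mouse cortex and hippocampus were measured by MALBAC-DT, a plate-based method that amplifies complementary DNA in looping cycles and tags each molecule with a unique molecular identifier (UMI). The labels list 42 plates of 96 wells: 2 tissues, 7 ages (postnatal days P1, P7, P14, P21, P28, P56 and P180) and 3 plates for each pair of tissue and age. The organism label of the samples names human, but the series title, the mouse strain, the build mm10 (per the submitters' processing notes) and the gene symbols are those of mouse, and the samples were treated as mouse. The aligner and the program that counted genes are not given in the sources used here, and neither is the use of strand in counting. Gene positions were not used here.

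The deposited count tables hold UMI counts per nucleus and gene with no normalization. The authors' filtered table holds 3517 nuclei and 40760 genes, and their table before filtering holds 4032 wells with 92 ERCC spike-in columns. The 2 tables were checked against each other and differed at 0 values for the nuclei and genes they share. Per the file headers, the authors also gave quality values per well as a fraction (mitochondrial UMIs, ERCC UMIs, assigned reads and mapped reads), a correlation score and read counts. The authors' filter used 12 criteria per well, and the wells that met all 12 were the 3517 in the filtered table. Thresholds of that filter are not given in the sources used here.

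The filtered UMI counts were used throughout. Plates were taken as replicates, and UMIs were summed over the nuclei of each plate, or over the nuclei of 1 cell class on each plate where at least 5 nuclei of the class were present. The labels do not say whether plates of a group come from different animals, so p-values measure only the spread between plates, which may be technical. Plate totals ranged from 532999 to 1791678 UMIs. Intervals and floors cover counting error only, with exact Clopper-Pearson limits at 95% for shares. A fold against a group with 0 UMIs is a lower bound from a floor of 3 UMIs over the group, and a group with 1 to 3 UMIs gives a ratio with its exact counting interval.

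Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, totals were scaled by TMM, and glmQLFit with glmQLFTest was fitted on group means over all 42 plates. Fits of excitatory neurons used the plates of 1 tissue, and fits of inhibitory neurons and astrocytes used both tissues with tissue and age as terms. A gene is called where its p after Benjamini-Hochberg adjustment is under 0.05, and every adjusted p of a gene below is from this edgeR quasi-likelihood test unless another tool is named. Log2 fold changes are given with a standard error (SE), obtained as the size of the change divided by the root of the F statistic. Levels are CPM, UMIs of a gene scaled to a common plate total. The tools were tested on simulated data: with 3 plates against 3, the fit of all nuclei found 37% of genes changed 2-fold and 87% of genes changed 4-fold, with 3.12% false calls. In astrocytes these shares were 3% and 33%, with 2.7% false calls. The highest shares of false calls were 6.1% for hippocampus against cortex and 4.92% in hippocampal excitatory neurons. Changes were planted only in genes above a set mean CPM, so the shares found do not hold for scarcer genes.

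Gene lists fixed before the data were examined were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists of a contrast. The 24 lists cover immature neurons, axon guidance, NMDA receptors, AMPA and kainate receptors, GABA-A receptors, chloride transporters, postsynaptic density, presynaptic release and voltage-gated channels. They also cover myelin, mature astrocytes, cell cycle, activity-regulated genes, perineuronal net, cholesterol synthesis, DNA methylation, chromosome architecture, cell adhesion, and imprinted and nuclear noncoding RNA. The last of them cover hippocampal field, neocortical layer, interneuron subtype, mitochondrial-encoded and ribosomal protein genes. The mitochondrial-encoded and ribosomal protein lists were set as measures of quality. Named genes follow a rule fixed before the data were examined. It takes up to 12 genes each way with the largest log2 fold change among called genes with a change of at least 1, an average log2 CPM of at least 4, and plates of both groups that do not overlap. Mitochondrial-encoded, ribosomal protein and predicted genes are left out of the 12, and members of the lists may also be named. Genes outside both are marked as chosen after their values were seen.

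Cell classes were obtained with numpy 2.4.6 and scikit-learn 1.9.0 under Python 3.11.15. Counts were scaled per nucleus and logged, and 2000 variable genes were reduced to 30 principal components. A graph weighted by the neighbours that nuclei share, out of 15 each, was split by leidenalg 0.10.2 at resolution 1 into 27 clusters. Clusters were named from markers fixed before the data were examined. Excitatory-like clusters (1711 nuclei) were led by Lamp5, Dsp, Neurod1, Fibcd1, Tshz2 or Tle4. Inhibitory-like clusters (447) were led by Sst, Vip or Sp9. Astrocyte-like clusters (316) were led by Tnc or Gjb6, oligodendrocyte-precursor-like nuclei (OPC; 181) by Pdgfra, and oligodendrocyte-like clusters (349) by Mal, Mog or Bcas1. Microglia-like clusters (298) were led by Inpp5d or Ctss, Cajal-Retzius-like nuclei (26) by Trp73, cycling-like nuclei (29) by Mki67 and mural-like nuclei (17) by Abcc9. A cluster of 44 nuclei with mixed vascular markers and a cluster of 99 nuclei led by Tac1, Rgs9 and Drd1 stayed unnamed. Class names are written without "like" from here on. For 72.6% of nuclei the class was also the one with the highest marker score of that nucleus. Nuclei of unnamed clusters count as not alike in this share. Scrublet, run through scanpy 1.11.5 at an expected rate of 0.05, marked 3 nuclei (0.0853%), too few to show that doublets were found. No nucleus was removed.

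Shares of classes were compared between early plates (P1 and P7, 6 per tissue) and late plates (P28, P56 and P180, 9 per tissue) with a two-sided exact permutation test, adjusted over 10 shares. A maturation score took genes called and changed at least 2-fold from P7 to P28 in the other tissue, as mean log2 CPM of higher genes minus lower genes. It was placed on a scale with P7 at 0% and P28 at 100%. Genes per nucleus were also counted after thinning each nucleus to 3000 UMIs, which left out 144 nuclei.

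Alternatives were DESeq2 1.42.0, its size factors within edgeR (RLE), no filter on low counts, nuclei before the authors' filter, plate number as a block, and fits of only the compared plates. Limma with trend on mean CPM per nucleus (log2 of CPM plus 1), plates left out in turn, at least 10 nuclei per plate, removal of marked doublets, classes by highest marker score, and resolution 2 were also run. Levels of genes of the sex chromosomes that tell the sexes apart were left out. Tables of reads per well that repeat other files were not used here. Values of some genes are not reported here.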

Results

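The data are UMI counts of 3517 nuclei from the cortex and hippocampus of mice at 7 ages between P1 and P180, on 3 plates for each of 14 groups. Each plate kept 41 to 93 nuclei after the authors' filter. The nuclei held 45046492 UMIs, with a median of 10823 UMIs (1714 to 49792) and 3289 genes per nucleus. The nuclear noncoding RNA Malat1 took 5.36% of all UMIs and Meg3 took 2.08%. Of the reads of the median nucleus, 93.6% mapped and 24.3% of the uniquely mapped reads were assigned to a gene. Comparisons ask which genes and cell classes change with age in each tissue, and which differ between the tissues.

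The oligodendrocyte share of nuclei rose from 0.384% ± 0.595 (SD, n = 6 plates) at P1 and P7 to 13.4% ± 4.46 (SD, n = 9) at P28 to P180 in cortex, with an exact permutation p adjusted to 0.001. In hippocampus 0 of 259 nuclei at P1 and 0 of 267 at P7 were oligodendrocytes, and the late share was 24.5% ± 10.98 (SD, n = 9; exact permutation p adjusted to 0.002). The hippocampal oligodendrocyte share was 2.32% at P14, 9.90% at P21, 33.0% at P56 and 28.5% at P180. Astrocytes fell from 21.7% ± 1.04 to 4.24% ± 2.50 of hippocampal nuclei (exact permutation p adjusted to 0.001, n = 6 and 9), by 17.4 points, or 8.69 points with classes taken from marker scores. They fell from 11.1% ± 4.65 to 5.33% ± 3.22 in cortex (exact permutation p adjusted to 0.0244, n = 6 and 9), a call lost when classes were taken from marker scores or when plates of 1 number were left out. Excitatory neurons fell by 9.71 points in hippocampus, from 47.6% ± 4.47 to 37.9% ± 6.09 (exact permutation p adjusted to 0.020, n = 6 and 9), and this difference changed sign under marker scores and missed the threshold without plates 2 or 3. Shares of cortical excitatory neurons (-6.24 points), inhibitory neurons (-4.81 points in cortex, -0.20 in hippocampus) and OPC (-1.25 in cortex, -4.65 in hippocampus) did not pass the adjusted threshold. The early and late plates leave out P14 and P21. Hippocampal excitatory neurons made up 69.88% ± 4.66 of nuclei at P14 and 61.15% ± 5.86 at P21 (SD, n = 3). Both shares lie above the early and the late mean, so the lower late share of this class is not a steady fall with age. The share of a class depends on which other nuclei were sampled and passed the authors' filter, and cortex P14 lost the most wells.

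**Figure D1:**
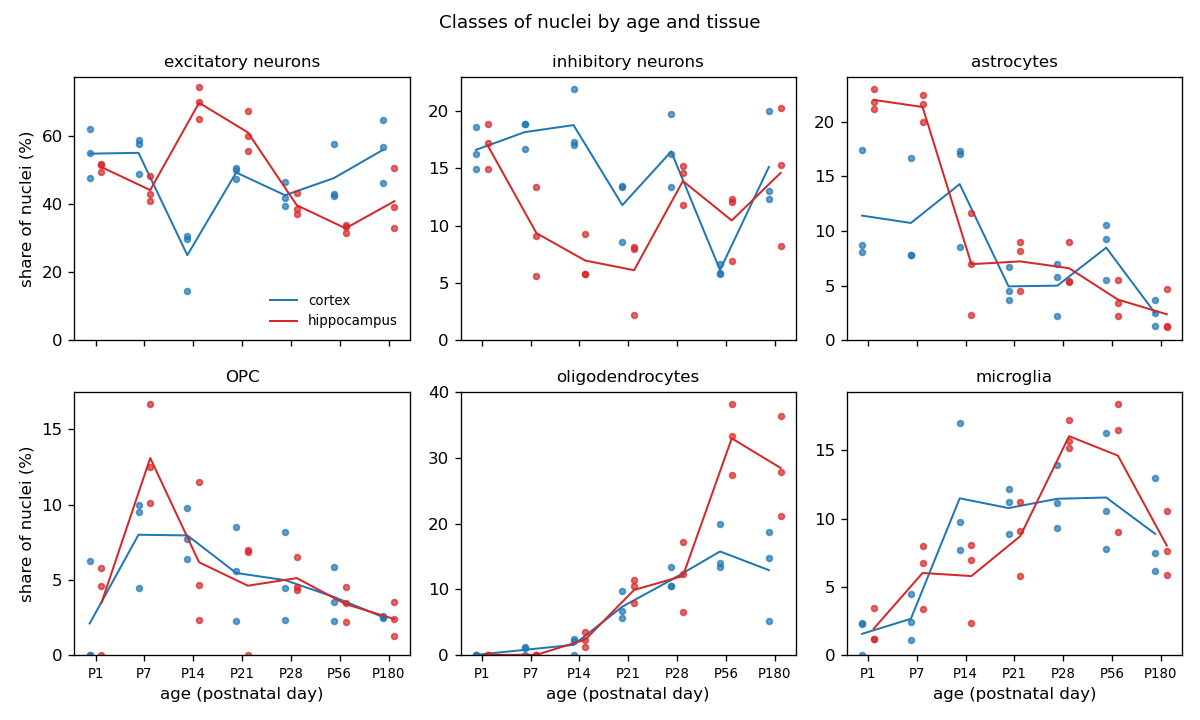
Share of nuclei (%) of 6 cell classes against age, in cortex and hippocampus. Points are plates and lines join the means of 3 plates; oligodendrocytes made 0% of hippocampal nuclei at P1 and P7 and 33.0% at P56.

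From P7 to P28 in cortex, 2905 of 14450 genes were called, 1564 higher and 1341 lower at P28. Of the called genes, 2708 had plates that did not overlap. Chance gives 10% of unselected genes for 3 plates against 3. Called genes were selected for a difference on these same plates, so such counts are no separate support. The myelin genes rose: Mbp, which compacts the sheath, went from 27.7 ± 21.2 to 1103 ± 163 CPM (SD, n = 3), a log2 change of 5.28 ± 0.45 (SE). Mobp, another myelin basic protein, rose by 9.66 ± 0.48 on the log2 scale, and Mal, Mag and Mog rose by ratios of 321 (109 to 1560), 209 (57.2 to 1730) and 167 (56.7 to 815). Sec14l5 rose at least 113-fold and Hapln2, a matrix link protein of nodes, at least 36.7-fold. Genes of immature neurons fell: Tubb2b, a tubulin of growing neurites, dropped from 978 ± 251 to 33.6 ± 20.2 CPM (SD, n = 3), a log2 change of -4.84 ± 0.32 (SE; edgeR adjusted p 9.15e-15). Cd24a, a surface glycoprotein of young neurons, changed by -4.03 ± 0.49, Stmn1, which destabilises microtubules, by -2.61 and Gap43, of growth cones, by -2.37. Dpysl3, a growth cone protein, changed by -3.10 ± 0.25, and Sox11, a transcription factor of newborn neurons, by -2.11 ± 0.27. St8sia2, which adds polysialic acid to the adhesion molecule Ncam1, fell by 5.28 on the log2 scale, the matrix protein Tnc by 5.33 and the radial glial Fabp7 by 3.35. Trim67, a ubiquitin ligase of growing axons, changed by -4.77 ± 0.55, the guidance ligand Draxin by -3.85, the connexin Gjc1 by -3.80 and the growth factor receptor Met by -3.61. Tubb2b, Tubb3 and Tuba1a have near-identical copies, and how reads shared by them were counted is not given in the sources used here, so their values are uncertain.

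In hippocampus the same step called 2821 of 14450 genes, 1492 higher and 1329 lower, and 2578 had plates that did not overlap. Tubb2b fell from 1431 ± 85.7 to 106 ± 47.4 CPM (SD, n = 3), a log2 change of -3.75 ± 0.29 (SE; edgeR adjusted p 7.18e-13). Fabp7 changed by -4.98 ± 0.35, Dpysl3 by -3.38 ± 0.25 and Nrep, a regeneration-related protein, by -3.25. St8sia2 changed by -3.29, Draxin by -3.44, Trim67 by -3.54 and Tnc by -5.19, all in the direction seen in cortex. The neuropeptide gene Nts changed by -4.30. Mobp was at least 1520-fold higher at P28 and the myelin glycoprotein Mog at least 119-fold and the claudin Cldn11 of myelin tight junctions at least 39.7-fold, while Mal rose by a ratio of 595 (106 to 23500). Both tissues shared 715 higher genes where 161.5 are given by independent lists, and 565 lower genes where 123.3 are. Another 20 and 12 genes were called in opposite directions, and the log2 changes had a Pearson r of 0.569 and a Spearman rho of 0.515 across genes, which are not independent replicates. Ttr, the transthyretin gene of choroid plexus, was at least 2620-fold higher at P28 in hippocampus, but 68.8% of its UMIs came from 1 nucleus.

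**Figure D2:**
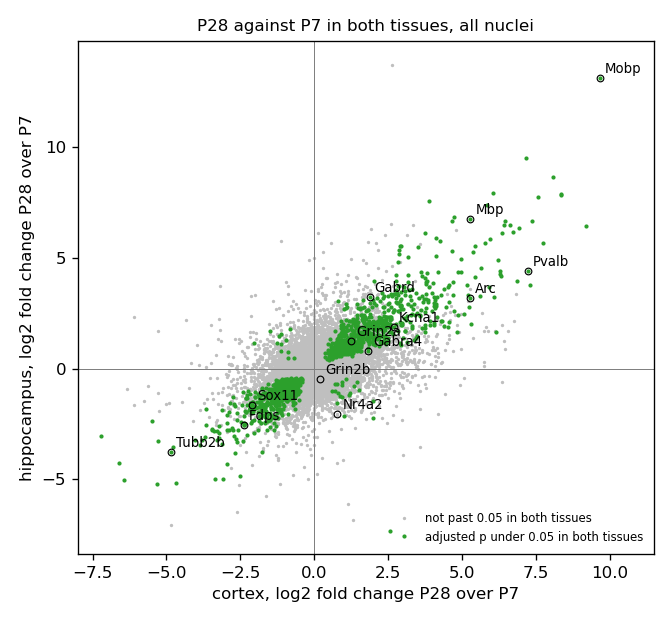
Log2 fold change from P7 to P28 in cortex (x axis) against hippocampus (y axis) for the 14450 genes tested; green points passed the adjusted threshold in both tissues. Tubb2b lies at -4.84 and -3.75 and Grin2a at 1.26 and 1.23, while positions of genes with 0 UMIs in a group (Mobp in hippocampus, Pvalb in cortex) depend on the prior count of the fit.

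Some synaptic and channel genes also changed over this step. The NMDA receptor subunit Grin2a rose by 1.26 ± 0.24 in cortex (SE; edgeR adjusted p 0.000108), from 152 ± 8.94 to 363 ± 129 CPM (SD, n = 3), and by 1.23 ± 0.23 in hippocampus (edgeR adjusted p 0.00016). Grin2b, the subunit of young synapses, changed by 0.21 ± 0.17 and -0.45 ± 0.17, and neither passed the adjusted threshold. The AMPA subunit Gria3 rose by 1.39 in cortex and 1.01 in hippocampus, and the kinase subunit Camk2a by 1.89 and 1.51. The potassium channel gene Kcna1 rose by 2.69 ± 0.24 and 1.87 ± 0.23. The sodium channel gene Scn3a of immature neurons changed by -1.08 ± 0.19 in cortex. The GABA-A subunit gene Gabra4 rose by 1.83 ± 0.27 in cortex, while Gabrd, of extrasynaptic receptors, rose by 3.24 ± 0.71 and Gabra3 changed by -1.28 ± 0.34 in hippocampus. Snap25, of the release machinery, rose by 0.92 in cortex and 0.89 in hippocampus. The activity-regulated gene Arc rose by 5.26 ± 0.96 in cortex (SE; edgeR adjusted p 0.000102) and 3.21 ± 0.83 in hippocampus (edgeR adjusted p 0.005). The neurotrophin Bdnf rose by 2.48 ± 0.61 in cortex. Dlgap1, a scaffold of the postsynaptic density, rose by 1.08 ± 0.15 in hippocampus, and the vesicle gene Vamp1 by 1.59 and the channel gene Kcna2 by 1.99 ± 0.26 in cortex.

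Genes of cholesterol synthesis fell from P7 to P28 in both tissues. Fdps, which makes farnesyl diphosphate, changed by -2.38 ± 0.48 in cortex (SE; edgeR adjusted p 0.000267) and -2.53 ± 0.49 in hippocampus (edgeR adjusted p 0.000201). The squalene oxidase Sqle changed by -1.73 and -2.11, and the synthase Hmgcs1 by -1.30 and -1.68. The demethylase Cyp51 changed by -1.26 and -1.81. Malat1 rose by 1.01 ± 0.12 and 1.26 ± 0.12, and the paraspeckle RNA Neat1 by 2.00 and 2.12. The cohesin subunit Smc1a changed by -1.01 and -1.04, and Mbd5, a methyl-CpG-binding-domain protein, by 0.78 and 1.06. The DNA methyltransferase Dnmt1 changed by -1.59 ± 0.40 in hippocampus.

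The immature neuron list fell with 0 higher and 16 lower of 17 genes in cortex (16 adjusted over the list alone; median log2 change -2.38; camera adjusted p 1.43e-28) and 17 of 17 in hippocampus (17 adjusted over the list alone; median -2.52). Of 15 myelin genes, 15 rose in cortex (15 adjusted over the list alone; median 5.84) and 14 in hippocampus (15 adjusted over the list alone; median 6.65, or 6.34 with 3 genes at their bound). Cholesterol synthesis had 9 of 14 genes lower in cortex (10 adjusted over the list alone; median -0.92; camera adjusted p 1.25e-06) and 10 of 14 in hippocampus (13 adjusted over the list alone; median -1.29). These 3 lists also passed camera with an estimated correlation in both tissues, as did hippocampal ribosomal protein genes (47 of 78 lower, 54 adjusted over the list alone). Axon guidance genes were lower at 6 of 20 in cortex (7 adjusted over the list alone) and 9 of 20 in hippocampus (11 adjusted over the list alone), where 4 were higher. Among these the receptor Nrp2 changed by -1.54 ± 0.27 and the ligand Slit1 by 1.85 ± 0.39 in hippocampus. Postsynaptic density genes were higher at 4 of 17 in cortex and 7 of 17 in hippocampus (4 and 9 adjusted over the list alone), and presynaptic genes at 5 of 17 and 4 of 17 (7 and 4 adjusted over the list alone). Activity-regulated genes were higher at 5 of 10 in cortex (5 adjusted over the list alone; camera adjusted p 0.0124, 0.132 with the estimated correlation). Chromosome architecture genes were lower at 4 of 15 in cortex and 7 of 15 in hippocampus (4 and 8 adjusted over the list alone). Imprinted and nuclear noncoding RNA had 6 of 12 higher in hippocampus (8 adjusted over the list alone), and cell cycle genes had 4 of 14 lower there (8 adjusted over the list alone).

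Receptor, transporter and adhesion lists mostly had no camera call at this step. Higher and lower counts in cortex were 2 and 0 of 5 NMDA receptor genes, 1 and 0 of 9 AMPA and kainate receptor genes, and 1 and 0 of 5 chloride transporters. They were 6 and 2 of 15 mature astrocyte genes, 3 and 3 of 9 perineuronal net genes, 3 and 2 of 9 DNA methylation genes, and 3 and 3 of 18 cell adhesion genes. Interneuron subtype genes had 4 higher and 1 lower of 13 in cortex, where Pvalb, of fast-spiking interneurons, had 0 UMIs at P7. GABA-A receptor genes, with 4 higher of 12 in cortex, passed camera there at the preset correlation (adjusted p 0.023) and not with the estimated correlation (0.218). Adjusted over the list alone, the higher counts in cortex were 2 NMDA, 1 AMPA and kainate, 2 chloride transporter, 8 mature astrocyte, 4 perineuronal net, 4 DNA methylation, 5 cell adhesion, 6 interneuron and 4 GABA-A genes. Over all contrasts, 111 of 307 list tests passed camera at the preset correlation and 41 passed with the estimated correlation. All 41 were among the 111. Fry, which does not compare a list with other genes, passed 146.

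The first postnatal week, P7 against P1, called 1463 of 14450 genes in cortex (894 higher, 569 lower; 1393 with plates apart) and 1494 in hippocampus (911 higher, 583 lower; 1406 with plates apart). In cortex the zinc transporter Slc30a3 of glutamatergic vesicles rose by a ratio of 17.4 (5.8 to 86.0), and Lin7b, a scaffold of synapses, rose by 3.65 ± 0.39 on the log2 scale (SE). Nrgn, which binds calmodulin in dendrites, rose by 2.55 ± 0.39 in cortex (edgeR adjusted p 1.65e-05) and 2.60 ± 0.39 in hippocampus (edgeR adjusted p 9.21e-06). The vesicle gene Syn2 rose by 1.89 ± 0.21 in cortex and 1.29 in hippocampus. Grin1, the obligate NMDA subunit, rose by 1.12 ± 0.22 in cortex, and Grin2a by 1.17 ± 0.25 in hippocampus. The chloride exporter gene Slc12a5 rose by 1.16 ± 0.23 in cortex (edgeR adjusted p 0.000563) and by 2.28 ± 0.25 in hippocampus (edgeR adjusted p 3.28e-08), from 38.8 ± 8.39 to 189 ± 29.8 CPM there (SD, n = 3). Gabra2 changed by -1.33 ± 0.18 and -1.29 ± 0.17. The potassium channel genes Kcna2 (1.42 ± 0.31) and Kcnt1 (1.53 ± 0.29), the active zone scaffold Bsn (1.36 ± 0.24), the long noncoding RNA Snhg11 (1.45 ± 0.19) and the astrocytic transporter Slc1a2 (1.62 ± 0.28) also rose in cortex. The transcription factors Bcl11b (-2.29 ± 0.22), Zfhx3 (-3.20 ± 0.41), Sox4 (-1.63) and Sox11 (-1.27) fell in cortex. The cluster led by striatal genes held 27 of 253 cortex nuclei at P1 and 0 of 264 at P7. Falls in cortex over this step may go in part with such nuclei. Leaving them out did not move the count of called genes by more than 1.5 times, but values of single genes without them are not given here. Igfbpl1, of newborn neurons, changed by -3.12 ± 0.50 and the adhesion molecule Cntn2 by -1.29 ± 0.28 in cortex. In hippocampus Camk2a (2.46), Sv2b (2.13), Cpne6 (3.75 ± 0.47) and the microglial receptor P2ry12 (4.01 ± 0.94) rose. Acan, the core proteoglycan of perineuronal nets, rose by a ratio of 25.8 (8.65 to 127), and C1ql3, a synaptic organiser, by 2.67 ± 0.46. Ttr was lower at P7 in hippocampus at least 633-fold, with 0 UMIs against 1098.

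Axon guidance genes fell over the first week, with 5 of 20 lower in each tissue (8 in cortex and 6 in hippocampus adjusted over the list alone), among them the guidance receptor Unc5d (-1.98 ± 0.34) and the repellent Sema3a (-2.19 ± 0.52) in hippocampus. That list passed camera with the estimated correlation in both tissues. NMDA receptor genes (2 of 5; 4 adjusted over the list alone; median log2 change 1.05, or 0.88 with 1 gene at its bound) and presynaptic genes (7 of 17; 9 adjusted over the list alone) did so in hippocampus, and the tissues were not tested against each other at this step. In cortex postsynaptic density genes (6 of 17), presynaptic genes (5 of 17) and voltage-gated channels (5 of 17) were higher, and passed only at the preset correlation. Adjusted over the list alone, their higher counts were 9, 6 and 7. Both tissues shared 371 higher genes (56.4 for independent lists) and 161 lower genes (23.0).

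From P28 to P180, 641 of 14450 genes were called in cortex (283 higher, 358 lower; 612 with plates apart) and 1122 in hippocampus (595 higher, 527 lower; 1030 with plates apart). Median UMIs per nucleus, as means over plates, fell from 11753 to 6228 in cortex and from 10640.5 to 7428 in hippocampus. The assigned share of uniquely mapped reads rose from 23.8% to 28.6% and from 22.1% to 29.7%. These differences of the libraries were not separated from age, so the calls may hold both. Neurofilament genes Nefh (2.90 ± 0.45) and Nefm (1.91 ± 0.29) and the guidance ligand Sema7a (3.04 ± 0.48) rose in cortex. Sema7a also rose by 2.32 ± 0.49 in hippocampus. The potassium channel gene Kcnq3, of the M-current, rose by 1.01 and 1.05, and the calcium sensor of release Syt1 by 0.94 ± 0.19 in cortex. Dcx (-1.33 ± 0.19), Sox11 (-1.98 ± 0.31) and Igfbpl1 (-3.83 ± 0.77), of immature neurons, fell in hippocampus, where Draxin, a guidance ligand, was at least 7.53-fold lower. Mobp changed by -1.69 ± 0.28 in cortex and -1.46 ± 0.27 in hippocampus, and 1 alternative of 15 lost each call. Trf, the transferrin of oligodendrocytes, rose by 2.43 ± 0.46 in hippocampus, Sv2a, of synaptic vesicles, by 1.47 ± 0.19, and Epdr1, an ependymin-related protein, by 2.05 ± 0.36. Frmd4a, a cell polarity scaffold, changed by -2.69 ± 0.28 there, and Nckap5 by -3.24 ± 0.49 in cortex. Vip was at least 151-fold higher in hippocampus, but 59.6% of its UMIs came from 1 nucleus. Presynaptic genes (7 of 17, 7 adjusted over the list alone) and voltage-gated channels (7 of 17, 9 adjusted over the list alone) were higher in cortex. GABA-A receptors (5 of 12, 8 adjusted over the list alone) and voltage-gated channels (6 of 17, 12 adjusted over the list alone) were higher in hippocampus. All 4 passed camera with the estimated correlation. Both tissues shared 141 higher genes (11.7 for independent lists) and 114 lower genes (13.1).

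**Figure D3:**
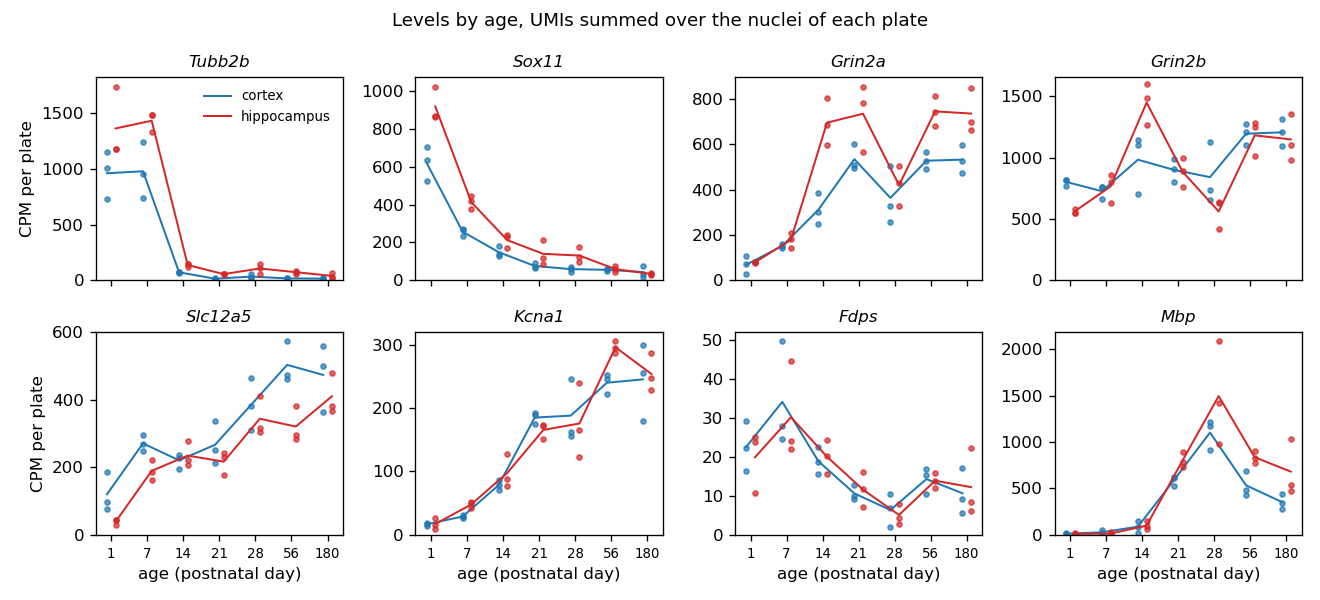
CPM of 8 genes against age, per plate, in cortex and hippocampus. Tubb2b fell from 978 CPM at P7 to 33.6 CPM at P28 in cortex, and Mbp rose from 27.7 to 1103 CPM.

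Averaged over the 7 ages, hippocampus and cortex differed at 3202 of 14450 genes, 1615 higher and 1587 lower in hippocampus, of which 615 changed at least 2-fold and 1041 had the same sign at every age. Zbtb20, a transcription factor of hippocampal fields, was higher by 2.24 ± 0.09 (SE; edgeR adjusted p 1.33e-22, 21 plates against 21). Prox1, of the dentate gyrus, was higher by 2.72 ± 0.11, the calcium-binding Calb2 by 2.18 and the guidance ligand Sema3c by 2.13. Fibcd1, a marker of the CA1 field, was higher by 3.16 ± 0.33 and the mineralocorticoid receptor Nr3c2 by 1.96 ± 0.14. Cortical layer genes were lower in hippocampus: Rorb by -1.89 ± 0.19, Foxp2 by -2.48 ± 0.22, Cux2 by -1.59 and Syt6 by -2.46. The heparan sulfate enzyme Hs3st2 (-2.28), the ephrin Efna5 (-2.03) and the sodium-activated potassium channel gene Kcnt1 (-1.14) were lower too. The hippocampal field list had 10 of 15 genes higher (11 adjusted over the list alone) and the neocortical layer list 12 of 15 lower (12 adjusted over the list alone; median -1.19), and both passed camera with the estimated correlation. Cell adhesion genes were lower at 9 of 18 (10 adjusted over the list alone), among them Cdh13 (-0.96 ± 0.08), and chromosome architecture genes higher at 7 of 15 (8 adjusted over the list alone). The striatal gene Drd1 (-3.20 ± 0.25) was also lower in hippocampus, and 97 nuclei on cortex plates fell in a cluster led by striatal genes.

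The change from P7 to P28 differed between the tissues at 251 of 14450 genes, 125 with a higher and 126 with a lower change in hippocampus. The kinase gene Dgkh had a change higher by 2.22 ± 0.29 in hippocampus (SE; edgeR adjusted p 8.79e-06), the channel gene Trpm3 by 3.21 ± 0.54 and Echdc2, of a family of enoyl-CoA hydratases, by 3.20 ± 0.59. The cathepsin gene Ctss of microglia had a change lower by -5.66 ± 1.03, the interferon receptor gene Ifngr1 by -3.55, the copine gene Cpne9 by -3.47 ± 0.66, the adrenergic receptor gene Adra2c by -3.45 and the teneurin Tenm4 by -1.46 ± 0.27. The difference for Grin2a was -0.03 ± 0.33 and for Tubb2b 1.10, and neither passed the adjusted threshold. Mitochondrial-encoded genes, a list set as a measure of quality, had a lower change at 8 of 10 (9 adjusted over the list alone; median -1.86). This was the list call that held with the estimated correlation. The assigned share of uniquely mapped reads went from 21.7% to 23.8% in cortex and from 28.4% to 22.1% in hippocampus (means of 3 plates). A difference in preparation between the groups was not separated from the tissue difference, for this list or for the 251 genes.

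Within excitatory neurons, P28 against P7 called 2050 of 10610 genes in cortex (1123 higher, 927 lower; 1903 with plates apart) and 2033 of 11005 in hippocampus (1128 higher, 905 lower; 1857 with plates apart). Hippocampal plates held 37 to 43 nuclei of this class at P7 and 33 to 40 at P28. With classes by highest marker score they held only 15 to 18 and 8 to 19, so the class is uncertain there. Tubb2b changed by -5.29 ± 0.37 in cortex (SE; edgeR adjusted p 5.25e-12) and -3.91 ± 0.24 in hippocampus (edgeR adjusted p 7.88e-13). Trim67 was lower by a ratio of 149 (26.6 to 5920) in cortex, and Fabp7 by -5.81 ± 0.39 in hippocampus. Fabp7 also leads a cluster of astrocytes, and the part of RNA from other classes in its fall was not tested. Grin2a rose by 1.33 ± 0.24 and 1.35 ± 0.17, and Gria3 by 1.87 ± 0.18 and 1.41. Gabra4 rose by 2.05 ± 0.35 in cortex, and Gabrd by 3.28 ± 0.73 in hippocampus. Grin3a, a subunit that limits synapse growth, changed by -2.98 ± 0.42 in hippocampus, where Gabra3 changed by -2.18 ± 0.58. The activity-regulated genes Egr1 (2.26 ± 0.43) and Bdnf (3.08 ± 0.66) rose in cortex. Lamp5, of upper layers, rose by 6.12 ± 0.60 in cortex, and the dentate gene Dock10 by 3.73 ± 0.42 in hippocampus, where the adhesion molecule Cntn2 changed by -2.57 ± 0.28. In hippocampus the synaptic organiser C1ql2 (4.16 ± 0.98) and the cation channel gene Trpc6 (4.82 ± 0.52) rose, and the neuropeptide gene Nts was lower by a ratio of 226 (40.2 to 8950). In cortex Zfp831, a zinc finger gene, was at least 43.0-fold higher, Kcna2 rose by 2.55 and Homer1, of the postsynaptic density, by 1.58, while Draxin was at least 12.5-fold lower. The sterol demethylase Cyp51 changed by -1.62 and -2.50 ± 0.38. Immature neuron genes were lower at 16 of 17 and 17 of 17 (the same counts adjusted over the list alone), and cholesterol genes at 8 of 13 in each tissue (9 adjusted over the list alone). Both lists passed camera with the estimated correlation, as did postsynaptic (6 of 16, 6 adjusted over the list alone) and presynaptic genes (5 of 17, 8 adjusted over the list alone) in cortex. The tissues shared 487 higher genes (108.2 for independent lists) and 374 lower genes (77.4). Most nuclei of the class lay in different clusters at the 2 ages: in cortex clusters 0 (Cd24a, Met) and 16 (Sox5, Tle4) at P7 and 4 (Pparg), 11 (Col5a1) and 5 (Lamp5) at P28. In hippocampus they were 8 (Neurod1, Prox1) and 22 (Crym) at P7, and 6 (Dsp, C1ql3), 10 (Fibcd1) and 8 at P28. Mbp stood at 467 CPM in excitatory neurons and 482 CPM in microglia at P28, so its rise in neurons is not read as expression there.

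Inhibitory neurons called 484 of 7708 genes from P7 to P28 over both tissues (300 higher, 184 lower). Tubb2b changed by -4.11 ± 0.43 (SE; edgeR adjusted p 1.53e-09), Fabp7 by -4.20 ± 0.54 and St8sia2 by -3.15 ± 0.63. Nrep changed by -2.59 ± 0.44, and Snap25 rose by 1.32 ± 0.25. Fam107a, an actin-bundling protein, rose by a ratio of 438 (78.1 to 17300), and Nrn1, a neuritin, by 71.3 (12.3 to 2860). Nrn1 is also among the markers fixed for excitatory neurons, and Fabp7 leads a cluster of astrocytes. RNA from other classes was not separated in these values, so they are not read as regulation within inhibitory neurons. The GABA-A subunit gene Gabra4 rose by 2.11 ± 0.55 and was called in 18 of 20 alternatives. Immature neuron genes were lower at 13 of 17 (14 adjusted over the list alone; median -1.77), a call that held with the estimated correlation. Cluster 12 grew from 12.5% to 41.9% of the class in cortex and from 4% to 52.6% in hippocampus, so the mix of subtypes differed between the ages. At resolution 2, 10 of its 18 cortical and 17 of its 20 hippocampal nuclei at P28 lay in a cluster led by Zic1 and Arhgap6, which held 0 nuclei at P7. The part led by Sp9 and Pbx3 went from 6 to 8 nuclei in cortex and from 1 to 3 in hippocampus.

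Astrocytes called 545 of 6090 genes from P7 to P28 over both tissues (246 higher, 299 lower; 6 plates at P7, 5 at P28). The gap junction gene Gjb6 rose by 4.14 ± 0.42 (SE; edgeR adjusted p 2.05e-10) and Gja1 by 2.13 ± 0.33. The NMDA subunit gene Grin2c rose by 5.08 ± 0.71 and Etnppl, a phospho-lyase of lipid metabolism, by 5.07 ± 0.73. Slc1a2, the main glutamate transporter, rose by 1.26 ± 0.23. The folate enzyme Aldh1l1 changed by -2.07 ± 0.49 and the phosphatase Ptprz1 by -1.69 ± 0.26. Ntsr2, a neurotensin receptor, rose by 3.23 ± 0.41 and Neat1 by 3.00 ± 0.40, while the matrix genes Vcan (-2.04) and Ncan (-1.73) and the lanosterol synthase gene Lss (-2.66) fell. The class held 85 nuclei at P7 and 29 on the P28 plates used. Of 15 mature astrocyte genes, 7 were higher and 1 lower (7 and 1 adjusted over the list alone), and 5 of 14 cholesterol genes were lower (6 adjusted over the list alone). Both lists passed camera with the estimated correlation. At P7 all nuclei of the class lay in cluster 2 (Tnc, Fabp7), and at P28 76.9% in cortex and 77.8% in hippocampus lay in cluster 18 (Gjb6, Etnppl). The median of all genes was -0.171 under TMM and 0.033 under DESeq2, a shift of 0.204 that leaves the directions of the genes named here as they are. Between the tissues, 5 of 6090 genes were called in astrocytes, all higher in hippocampus, against 482 at an unadjusted p under 0.05. Prox1 was higher by 3.08 ± 0.55 (edgeR adjusted p 0.00208), a call kept in 7 of 11 alternatives. Prox1 is also high in dentate neurons. It stood at 94.0 CPM in hippocampal and 17.3 CPM in cortical astrocytes, against 33.3 and 25.9 CPM in microglia and 77.8 and 25.6 CPM in OPC. In oligodendrocytes it stood at 141.3 and 154.8 CPM, and in inhibitory neurons at 75.1 and 81.5 CPM. A higher level in hippocampus was thus not particular to astrocytes, and the part of background in astrocytes was not separated.

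On the maturation scale, cortex stood at -10.4% ± 2.4 at P1, 34.5% ± 1.6 at P14 and 106.3% ± 3.7 at P21 (SD, n = 3). Hippocampus stood at -15.2% ± 5.3 at P1, 21.3% ± 5.5 at P14 and 90.2% ± 4.1 at P21 (SD, n = 3). At P56 and P180 cortex stood at 94.0% ± 3.7 and 94.3% ± 0.7, and hippocampus at 115.1% ± 5.1 and 111.9% ± 6.6. The cortical score used 1121 higher and 810 lower genes, among them Grin2a and Tubb2b, and the hippocampal score 1252 and 754. Genes chosen in the same tissue put P1 above P7 in both tissues, and put cortex P21 (83.4%) and hippocampus P56 (88.3%) and P180 (86.7%) below P28. Those genes were chosen on the same P7 and P28 plates that set the scale, which can by itself draw other ages inside it. The same-tissue score therefore cannot decide on which side of P7 or P28 these ages fall.

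**Figure D4:**
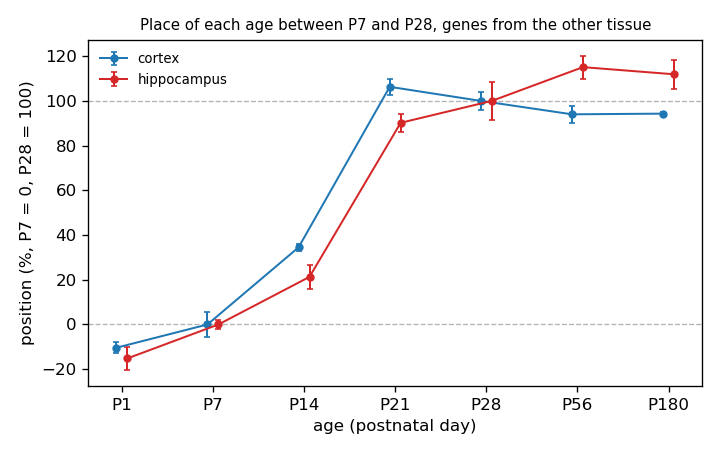
Position on the maturation scale (%, P7 at 0 and P28 at 100) against age in cortex and hippocampus. Points are means of 3 plates and bars are SD; P14 lies at 34.5% in cortex and 21.3% in hippocampus.

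Genes per nucleus at P28 minus P7 were -813.0 ± 212.2 in cortex and -526.5 ± 177.1 in hippocampus, and -86.7 ± 87.3 and -102.8 ± 51.9 after thinning to 3000 UMIs (SD, n = 3). Mitochondrial-encoded genes rose at 9 of 10 in cortex (median log2 change 0.90; 9 adjusted over the list alone) and fell at 8 of 10 in hippocampus (median -1.09; 8 adjusted over the list alone). Ribosomal protein genes had 30 of 78 lower in cortex (39 adjusted over the list alone; median -0.68). In cortex neither list passed camera with the estimated correlation.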

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

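Tests of a change of the mix of classes, of a steady change with age, of striatal genes with the background taken off, of doublets, of St18, of the myelin genes other than St18, of those over 1000 CPM in oligodendrocytes, and of shuffled residuals were chosen only after the results were seen, as were the draws that set the limit in the test of free RNA. The doublet test was last rewritten to use Mbp, with the share of nuclei with Mbp already known and its limits left as they were.

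The change from P7 to P28 differed between hippocampus and cortex at 251 genes, by a test of the difference itself. Of 100 arrangements of the plates, the real one included, 11 called as many, and the highest other called 1901 genes. That is several times the real count and points to a structure of the samples: all 10 others exchange unequal numbers of plates at the ages, which carries the tissue difference into the contrast. These arrangements therefore decide nothing about chance. With tissue and age effects taken off, the residuals of the 12 plates were shuffled. Only 1 of 100 orders, the real one, called as many genes by limma (156, highest other 1). That argues against a chance order of the plates for that count, but a difference shared by all plates of a group is not addressed. Among genes with a higher change in hippocampus, the log2 difference was 5.12 for the prostaglandin synthase gene Ptgds, 3.21 for the channel gene Trpm3 and 3.20 for Echdc2. It was 3.11 for Ccbe1, 3.05 for the phospholipase gene Pla2g4e, 2.77 for AI413582, 2.65 for Clvs2, 2.60 for the fibrillin gene Fbn1 and 2.42 for the replication gene Mcm6. Prdm8 followed with 2.34, the kinase gene Dgkh with 2.22 and the guidance ligand Slit1 with 2.19. Genes with a lower change in hippocampus were the peptide gene Vip, whose value of -9.89 is set by the prior count of the fit since it had 0 UMIs in hippocampus at P28, the microglial genes Ctss (-5.66), Olfml3 (-4.46), Cx3cr1 (-3.72) and Laptm5 (-3.71), and the receptor genes Cckbr (-3.82), Ifngr1 (-3.55) and Adra2c (-3.45). Csf1 (-3.51), Cpne9 (-3.47), Ankrd33b (-3.30) and the integrin gene Itgb5 (-3.19) complete this list. Ctss, Olfml3, Cx3cr1 and Laptm5 lead microglial cluster 19, which at P28 held 16 of 30 cortical and 0 of 44 hippocampal microglia, so their difference goes with this split. Ptgds took 89.8% of its cortex P7 UMIs from 1 nucleus.

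Cortex P14 plates had 148 of 288 wells outside the authors' filtered table, against 14 to 50 wells in the other groups, and no comparison used those wells as main data. Of the 148, 124 failed the authors' mitochondrial criterion. No explanation was tested. Astrocytes, called at 5 genes between the tissues, were the class result that moved when cortex P14 plates were left out.

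Other splits of the same plates were counted for each comparison. With 3 plates against 3, the 10 splits are too few for a share under 0.05, and the real split was the 1 with the most genes. For all nuclei, the real counts and the highest others in cortex were 1463 and 3 (P7 against P1), 2905 and 1 (P28 against P7), and 641 and 5 (P180 against P28). In hippocampus they were 1494 and 2, 2821 and 3, and 1122 and 8. Excitatory neurons gave 2050 and 2 in cortex and 2033 and 0 in hippocampus. In 4 comparisons with 100 splits each, only the real split (1 of 100) called as many genes. That argues against a chance assignment of plates but does not exclude it. A difference shared by all plates of a group, such as that of 1 animal, is not addressed by these splits. The 4 comparisons were hippocampus against cortex (3202, highest other 554), inhibitory neurons (484, highest other 59), astrocytes at P28 against P7 (545, highest other 247), and astrocytes between tissues (5, highest other 4). For the last the margin is 1 gene. Its count fell to 2 without cortex P14 plates, to 2 without replicate 1 or replicate 2, and to 0 with at least 10 nuclei per plate. The splits therefore decide little for astrocytes between tissues.

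Ribosomal protein transcripts had 30 of 78 genes lower at P28 than at P7 in cortex and 47 of 78 in hippocampus, and in cortex the list lost its camera call with the estimated correlation (adjusted p 0.132, against 0.0217 in hippocampus). A change of the mix of cell classes was tested within excitatory neurons, where the median log2 change of these genes was still -0.70, the one nearer 0 of both tissues, which argues against the mix as the whole cause. A difference in UMIs per nucleus was tested in nuclei of 8000 to 14000 UMIs: the ribosomal share at P28 was 71.7% of that at P7 in cortex (0.666% to 0.478%) and 55.8% in hippocampus (1.04% to 0.58%), with plates apart. That argues against depth as the whole cause. Less cytoplasmic RNA left on the nuclei could lower these transcripts. Of 24 listed cytoplasmic mRNAs, 23 had a value: their median log2 change was -0.21 ± 0.18 in cortex, with 13 below 0, and -0.46 ± 0.14 in hippocampus, with 21 below 0. The cortical value lies close to its error, so this explanation cannot be told apart from none, and mitochondrial-encoded genes rose in cortex over the same step. A biological change with age stays open and was untested.

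Nuclei led by the striatal genes Drd1, Tac1 and Rgs9 made up 27 of 253 cortex nuclei at P1, 0 of 264 at P7 (upper limit 1.39%), 21 of 140 at P14, 24 of 261 at P21, 13 of 262 at P28, 9 of 261 at P56 and 3 of 238 at P180. Hippocampus plates held 2. These counts depend on the clustering. At resolution 2 the cluster led by Rgs9, Tac1 and Penk held 2 cortex nuclei at P1, 0 at P7 and 21 at P14, and another, led by Rxrg and Scn9a, held 52, 3 and 0. A list of 12 striatal genes was used to ask whether clustering placed such nuclei elsewhere at P7. The highest cortex P7 plate reached 59.7% of the cortex P1 level, but hippocampus P7 plates reached 54.8%, so this test reads background and decides nothing. With the hippocampus level taken off, 16.7 ± 49.3 CPM were left at P7 against 277.8 ± 42.9 CPM at P1, which argues against that explanation. For the gap at P7, the larger of the Fisher exact p-values against P1 and P14 was 1.97e-09 at resolution 1. That test takes nuclei and not plates as units, and the gap itself prompted it, so it gives no independent support. The level of the 12 genes over hippocampus, which needs no clusters and uses plates, also dipped at P7 and stood at 1076.8 ± 549.2 CPM at P14. That dip argues against a steady change with age. A difference in the piece of tissue taken at each age may be the source, since plates of 1 age carried like shares at all ages (0 ages with plates that differ, exact p 0.505 to 1). That value cannot tell a dissection from a biological difference between ages, which stays open, and the labels name cortex only.

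Myelin transcripts were found in neurons at P28. Mbp gave a UMI in 77.8% of excitatory neurons at P28 (median 13087 UMIs), against 17.8% at P7 (median 19830 UMIs), and in 56.8% of microglia at P28 (median 6579 UMIs). Doublets of a neuron and an oligodendrocyte would have to make up 77.8% of these nuclei, at a mean of 491 CPM where oligodendrocytes had 7488 CPM, which argues against them. Free RNA from oligodendrocytes as the one source of all 15 listed genes is argued against. Over them the log2 ratio of excitatory neurons over microglia had an SD of 1.81, where 95% of draws of excitatory nuclei thinned to the microglial total stayed under 1.21. St18 drives this, with 124 UMIs in excitatory neurons and 0 in microglia (Fisher exact p 7.48e-08 against the other genes). St18 was picked as the extreme of the 15 genes, and the test takes UMIs as independent, so that p only describes the counts. With St18 left out the SD was 1.21 over 14 genes (limit of the draws 1.25, p 0.07), so for the scarce genes among them free RNA cannot be told apart from other sources at such low microglial counts. For the 4 genes over 1000 CPM in oligodendrocytes, with 91.5% of the myelin UMIs of excitatory neurons, free RNA may be the source: the SD of this log2 ratio was 0.15 and its median 0.04, so neurons had no excess over microglia. A biological source in neurons stays open for St18 and the scarce genes and was untested.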

How the results depend on the processing

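The leaving out of cortex P14 plates, of nuclei with striatal genes, and of unnamed nuclei from the shares were tests chosen only after the results were seen. Moved means by more than 1.5 times.

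None of 573 pairs of gene and comparison changed direction: of 8740 values under the alternatives, 8107 kept their side of the threshold, 610 fell short of it and 23 newly passed it. Of 545 called pairs, 401 were called under every alternative run. Grin2b in hippocampus from P7 to P28, not called in the main test, was called in 7 of 15 alternatives.

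Counts of called genes moved under 0 of 13 fits with RLE scaling, 0 of 8 with nuclei before the authors' filter and 0 of 8 without striatal-gene nuclei. They moved under 0 of 5 without marked doublets, but only 3 nuclei were marked, all of them excitatory neurons. The fits of inhibitory neurons and astrocytes were thus unchanged, and this alternative decides nothing about doublets. DESeq2 moved 1 of 13, astrocytes between tissues (29 genes against 5), and no filter moved that result to 27 and the tissue difference of P28 against P7 to 438 against 251. Limma on mean CPM gave 137 for that difference and 875 against 1463 for cortex P7 against P1. Fits of only the compared plates, with fewer samples to estimate the spread, gave 138 for the tissue difference, 275 against 641 for cortex P180 against P28 and 488 against 1122 for hippocampus. Classes by marker score gave 1139 against 2033 genes in hippocampal excitatory neurons, 331 against 545 in astrocytes from P7 to P28 and 20 between tissues. With at least 10 nuclei per plate, hence fewer plates, inhibitory neurons gave 291 against 484. Astrocytes between tissues then gave 0 by edgeR, with 612 at an unadjusted p under 0.05, and 2 with cortex P14 plates left out. Beyond fewer samples, the cause was not tested.

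Scaling moved the median of all genes by over 0.1 only in astrocytes from P7 to P28, by 0.204 with DESeq2 and 0.195 with RLE. The split of 246 higher and 299 lower became 358 and 255 with DESeq2 and 300 and 187 with RLE.

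Leaving out 1 plate at a time gave 825 to 1106 genes for cortex P7 against P1 (825, 948 and 860 without P1 replicates 1, 2 and 3, 937 without P7 replicate 3), 2266 to 2471 for cortex P28 against P7 and 383 to 518 for cortex P180 against P28 (383 and 389 without P28 replicates 2 and 3, 392 without P180 replicate 1). Hippocampus gave 939 to 1254 for P7 against P1 (959 and 939 without P1 replicates 1 and 3, 974 without P7 replicate 2), 2068 to 2388 for P28 against P7 and 553 to 1013 for P180 against P28 (616 without P28 replicate 1, 553 without P180 replicate 3). The tissue difference gave 122 to 245, with 122 and 166 without cortex P7 replicates 1 and 3, 156 without cortex P28 replicate 2, and 146 and 165 without hippocampus P7 replicates 2 and 3. Excitatory neurons gave 1554 to 1763 in cortex and 1532 to 1892 in hippocampus, inhibitory neurons 361 to 427, and astrocytes 409 to 530 from P7 to P28. Leaving out every plate of 1 number gave 2006 to 2371 between tissues (2006 without replicate 1), and 2 to 6 in astrocytes (2 without replicate 1, 2 without replicate 2).

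Oligodendrocyte shares and hippocampal astrocyte shares rose and fell under every alternative, though marker scores brought the fall to -8.69 points and the hippocampal rise missed the threshold with P7 against P28 and P56 (22.5 points, adjusted p 0.0595; 0.002 to 0.0595 over the alternatives). Marker scores turned the hippocampal excitatory difference to 2.31 points, brought cortical astrocytes to -1.26, and made cortical inhibitory neurons (-9.21), cortical OPC (-3.98) and hippocampal OPC (-4.91) pass. P7 against P28 and P56 brought cortical astrocytes to -4.00 and hippocampal excitatory neurons to -7.85, neither past the threshold, and hippocampal OPC to -8.85, past it. The cause was not tested. Leaving out a plate number gave, in cortex, -8.35 to -3.02 for excitatory neurons, -6.03 to -4.15 for inhibitory neurons, -7.62 to -3.45 for astrocytes (the call lost each time, at -6.18 without replicate 1, -3.45 without 2 and -7.62 without 3), 12.2 to 14.4 for oligodendrocytes and -2.31 to 0.41 for OPC. In hippocampus it gave -10.4 to -8.91 for excitatory neurons (lost at -8.91 without 2 and -10.4 without 3), -1.20 to 1.79 for inhibitory neurons, -17.9 to -17.2 for astrocytes, 22.3 to 26.6 for oligodendrocytes and -5.95 to -3.42 for OPC (called at -5.95 without replicate 1).

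Maturation positions with genes of the same tissue were 10.7 at P1, 44.2 at P14, 83.4 at P21, 89.3 at P56 and 88.9 at P180 in cortex, and 9.7 at P1, 51.7 at P14, 88.3 at P56 and 86.7 at P180 in hippocampus, so P1 changed sides in both tissues, and the cause was not tested. In excitatory neurons only, they were 43.0 at P14 and 92.4 at P180 in cortex, and -8.6 at P1, 32.3 at P14, 101.1 at P21 and 120.1 at P180 in hippocampus. Thinning brought genes per nucleus to -86.7 in cortex and -102.8 in hippocampus. With the estimated correlation 41 list calls stood, against 111.

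Plates of the same number were slightly closer: over 8931 genes their deviations had a mean r of 0.0107, against -0.0053 for different numbers, and 26 of 42 plates were closest to their own number, above the 1 in 3 of chance. In 0 of 91 group pairs was every r over 0.1. The replicate block moved 0 of 13 counts and no share call.

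Not run were astrocytes from P7 to P28 with at least 10 nuclei, since no P28 plate holds so many. At this depth and number of nuclei, astrocyte fits found 33% of simulated 4-fold changes from P7 to P28 and 71% between tissues.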

Other observations

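The microglia share and the values of single genes in this part were chosen only after the results were seen. Microglia rose from 2.09% ± 1.49 (SD, n = 6 plates) at P1 and P7 to 10.6% ± 3.32 (SD, n = 9) at P28 to P180 in cortex, a difference of 8.54 points (two-sided exact permutation p 0.0004). In hippocampus they rose from 3.97% ± 2.83 to 12.9% ± 4.65 (SD, n = 6 and 9), by 8.93 points (two-sided exact permutation p 0.0022). These p-values are unadjusted.

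Ttr, which choroid plexus expresses at high levels, gave a UMI in 79.5% of hippocampal nuclei at P1, in 0 of 267 at P7, in 0 of 259 at P14, and in 78.3%, 88.7%, 78.3% and 75.1% at P21, P28, P56 and P180. In cortex the share was at most 6.1%. Ttr therefore appears in the hippocampal comparisons of P7 with P1 and of P28 with P7. Over both tissues at P28 it gave a UMI in 45.3% of excitatory neurons and 52.7% of microglia, pooled over cortex, where few nuclei had one.

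Meg3 stood at a mean of 27019 CPM in excitatory neurons and 46353 CPM in inhibitory neurons at P28, against 979 CPM in microglia. Slc1a2 stood at 13616 CPM in astrocytes and 1148 CPM in excitatory neurons at P28.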
